A study of Daphnia pulicaria with 8 samples.

How the data were processed

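The material was whole adult Daphnia pulicaria, a water flea, from 4 lakes (Black, Doe, Long and Round) and of 2 colour phenotypes (Red and Pale). Each lake gave 1 Red and 1 Pale library, so there were 8 libraries, 4 per phenotype. Per the labels' protocols, 30 animals per lake were preserved and pooled, ribosomal RNA was depleted and directional libraries were made; whether the 30 animals were per phenotype is not stated in the labels. No lake and phenotype combination was repeated. In fits with lake and phenotype, the error behind the p-values is therefore how much the Red minus Pale difference varied between lakes.

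The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library) with 2 decimals, 1 table for 33069 genes and 1 for 109737 isoforms. The submitters' processing notes name Trimmomatic, a read trimmer; the aligner, the quantification tool and the genome build were not given in the sources used here. Each deposited gene FPKM equalled the sum over its isoforms to within 0.04. The authors also deposited a log2 ratio per lake, which in all 33069 genes and each lake equalled the log2 of Pale over Red FPKM with zeros set to 0.001 (tolerance 1e-09); it was not used, because its size for genes near 0 is set by that constant. Gene names were those in the deposited tables, with the trailing percentage removed; 18863 genes had a name other than uncharacterized, unknown or conserved protein. The identifiers are Daplx7pEVm gene models. Of the 33069 identifiers, 0 matched the RefSeq gene table of assembly SC_F0-13Bv2, so no coordinates are given.

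The number of reads per library is unknown. Low FPKM values of the 17402 genes with 1 isoform lie on steps as whole fragments would give, and the steps gave depths relative to Black Pale of 1.86 for Black Red and of 0.906 to 1.13 for the others. Counts could not be rebuilt from these steps, so no count model was run. FPKM sums ran from 543804 to 582444 per library, and 1 uncharacterized gene, Daplx7pEVm025448, held 41.0% to 48.1% of each sum. Its share was higher in Red than in Pale in each lake: 46.65% against 42.17% in Black, 48.12% against 47.05% in Doe, 46.96% against 45.52% in Long and 45.24% against 40.99% in Round. How far this lowered the FPKM of other genes in Red was not tested.

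Values were analysed as log2(FPKM + 1), which understates the change of low genes, for genes with a mean of at least 1 FPKM over the 8 libraries. Tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend, lake as a block and phenotype as a term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors on log2 differences are limma standard errors. Lakes were tested by an F test over the lake terms and by each lake against the mean of the other 3. Gene lists were 30 fixed name patterns, tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured. They were tested again with an estimated correlation and with fry. Estimating the correlation raised p even for lists whose estimate was below the preset one. A call lost there is therefore not evidence that a list did not change. The lists include markers of tissues whose share of the whole animal can differ (eye, gut, muscle, yolk, dividing cells and germ line). The globin list was also tested by an exact two-sided sign-flip test over the 4 lakes, whose smallest possible p is 0.125. Lists, designs and the rule for named genes were fixed before the data were examined, as were the settings except those for lists by lake and for variance shares, fry and an estimated correlation under other scalings, and lists without members of other function. By that rule, the text names genes of the same sign in all 4 lakes, those past the threshold first and then those with the smallest unadjusted p up to 10 per direction, at most 2 uncharacterized genes per direction, all measured globins, up to 4 members of each called list, up to 5 genes per lake and up to 5 isoforms per direction of genes not already named. Globins are given in groups.

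The lake is the pairing factor by design. The deviations of the Red and the Pale library of a lake from their phenotype means correlated across genes at 0.485 in Black, -0.015 in Doe, -0.021 in Long and 0.214 in Round, and 4 of 8 libraries correlated best with the other library of their own lake.

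The procedure was tested on simulated values with the fitted spreads of the 12865 genes, in 10 sets with 200 changed genes. For Red against Pale it called 30.4% of genes changed by 1 on the log2 scale, 73.7% of those changed by 2 and 86.1% of those changed by 3, with 7.4 false calls per set. A simulated list of 28 genes raised by 1 was found in 10 of 10 sets. For a lake difference of 3, the contrast of 1 lake recovered 86.0% and the F test 71.6% of changed genes, with 8.8 and 6.1 false calls per set. Simulated genes vary independently, unlike real ones. The changed genes were drawn at random and got the same shift in each lake. The shares called can therefore be too high for genes whose difference varied strongly between lakes. An example is the haemoglobin gene Daplx7pEVm013713, with a log2 difference of 0.634 in Doe and 6.478 in Long.

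Alternatives were other pseudocounts (0.1 and 5), no filter and a mean of at least 5 FPKM, median-of-ratios size factors, quantile normalization, no variance trend, robust variances, no lake block, and leaving out libraries. Figures were drawn with matplotlib 3.10.9.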

Results

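Transcript levels were measured in whole adults of the water flea Daphnia pulicaria of a Red and a Pale phenotype from each of 4 lakes, in a study whose title concerns hypoxia and metabolic phenotype. The 8 libraries held between 19274 and 21606 genes above 0 FPKM. Spearman correlations between 2 libraries ran from 0.77 to 0.888 over the 12865 genes analysed. Lake took 48.5% of the sum of squares, phenotype 15.8% and the residual 35.7%, against 42.9%, 14.3% and 42.9% of the degrees of freedom. The first principal component held 26.0% of the variance and placed Long Red (62.3) farthest from Doe Red (-34.0) and Black Pale (-32.9).

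Haemoglobin transcripts were more abundant in the Red library of every lake. Haemoglobin is the oxygen-binding pigment of Daphnia blood, and its genes form a family of similar copies. The summed FPKM of the 34 globin genes was 2066 ± 1051 in Pale and 4675 ± 731 in Red (SD, n = 4), a geometric mean ratio of 2.49 over the lakes. The ratio of Red to Pale was 4.15 in Round, 3.06 in Black, 1.96 in Long and 1.54 in Doe. The exact sign-flip test over the n = 4 lakes gave the smallest p this design allows, p = 0.13.

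**Figure D1:**
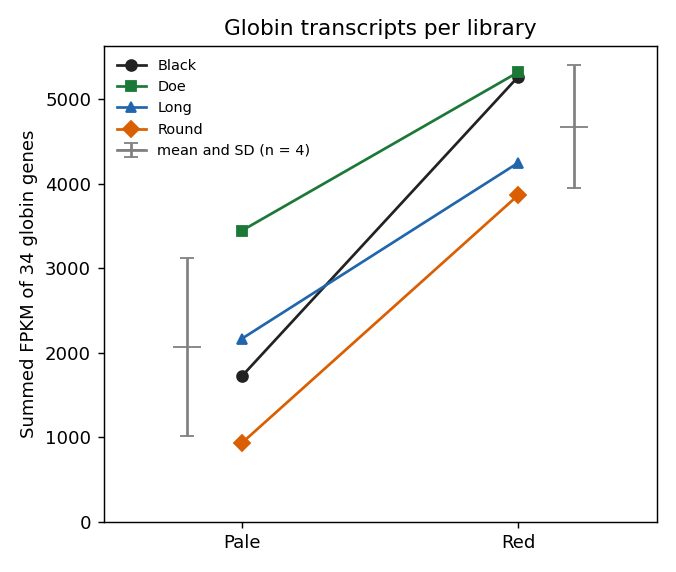
Summed FPKM of the 34 globin genes (vertical axis) in the Pale and the Red library of each lake, joined by lines, with the mean and SD of the 4 libraries of each phenotype in grey. Each of the 4 lines climbs, from 932 to 3865 FPKM in Round and from 3444 to 5320 FPKM in Doe.

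Of the 28 globin list members tested, 15 rose and 2 fell in Red when adjusted over the list alone, and 0 passed limma when adjusted over all 12865 genes. The gene named Globin (Daplx7pEVm022328) had 166.5 ± 86.5 FPKM in Pale and 657 ± 116 in Red (SD, n = 4), a log2 difference of 2.11 ± 0.38 (SE). The most abundant di-domain haemoglobin, Daplx7pEVm013675, had 494 FPKM in Pale and 962 in Red. Daplx7pEVm013713 had the largest log2 difference of the family, 3.81 ± 1.01, and Daplx7pEVm013338 had 3.33 ± 0.84. Further members that rose were the di-domain genes Daplx7pEVm025634, Daplx7pEVm011936, Daplx7pEVm058987, Daplx7pEVm016331, Daplx7pEVm012731, Daplx7pEVm013666, Daplx7pEVm023442, Daplx7pEVm011494 and Daplx7pEVm011714 and the Globin genes Daplx7pEVm059616 and Daplx7pEVm018448, with log2 differences from 0.81 to 2.54. The 2 that fell were Daplx7pEVm018901 (-1.31) and Daplx7pEVm013461 (-0.83), each lower in 3 lakes. Members that did not pass included Daplx7pEVm018111 (-0.74), Daplx7pEVm013589 (1.17), Daplx7pEVm017997 (1.42), Daplx7pEVm013392 (0.46), Daplx7pEVm013636 (0.46), Daplx7pEVm060678 (0.48), Daplx7pEVm013242 (0.15), Daplx7pEVm017006 (0.02), Cytoglobin Daplx7pEVm002298 (-0.98) and Cytoglobin-2 Daplx7pEVm018093 (0.00). The remaining member, Alpha-globin transcription factor CP2 (Daplx7pEVm002409), is a transcription factor and not a globin; its log2 difference was -0.04, with 0.05 after size factors and 0.17 after quantile normalization. The list had a median log2 difference of 1.21 and rose by camera with adjusted p = 1.53e-10, but adjusted p = 0.347 with an estimated correlation and 0.091 by fry; its median was 1.30 with size factors, 1.23 with quantile normalization, 0.73 with a pseudocount of 5 and 0.65 with no filter. Copies this similar can share reads, so values of single genes are less certain than the sum.

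Of the 9 hypoxia signalling genes, 3 rose in Red when adjusted over the list alone, 1 fell and 5 did not pass. The gene named Hypoxia-inducible factor 1-alpha, putative (Daplx7pEVm012460), the transcription factor stabilised at low oxygen, had 0.61 ± 0.43 FPKM in Pale and 2.59 ± 0.49 in Red (SD, n = 4). It rose by 1.18 ± 0.19 (SE) on the log2 scale, as did both prolyl hydroxylase genes of the list, whose products mark that factor for breakdown: Daplx7pEVm014955 by 1.70 ± 0.33 and Daplx7pEVm017444 by 1.04 ± 0.29. Von Hippel-Lindau disease tumor suppressor (Daplx7pEVm018967), part of the ligase acting after that mark, fell by 0.56 on the log2 scale. Each of the 4 kept its direction in 4 of 4 lakes, but Daplx7pEVm017444 differed by only 0.021 in Doe (1.74 FPKM in Pale, 1.78 in Red). That gene and Daplx7pEVm012460 were low in Pale, with means of 1.14 and 0.61 FPKM. The list (median 0.24, 0.16 without Long and 0.43 with quantile normalization) rose by camera with adjusted p = 0.0209, but adjusted p = 0.376 with an estimated correlation.

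Of 10 genes of haem synthesis and breakdown, 2 rose when adjusted over the list alone and 8 did not pass. Coproporphyrinogen-III oxidase (Daplx7pEVm011720) had 3.81 ± 0.67 FPKM in Pale and 7.17 ± 1.51 in Red (SD, n = 4), and Porphobilinogen deaminase (Daplx7pEVm011113) rose by 0.90 ± 0.24 (SE). Uroporphyrinogen decarboxylase (Daplx7pEVm013495) differed by 0.49 ± 0.30 and 5-aminolevulinate synthase (Daplx7pEVm008176), the first enzyme of the pathway, by 0.37 ± 0.28. The list rose by camera with adjusted p = 0.00455, but adjusted p = 0.347 with an estimated correlation, and without the Black pair the camera call was lost (adjusted p = 0.0962). Its median was 0.20, with 0.30 without Long and 0.09 with a pseudocount of 5. Of 22 iron storage and transport genes, the Ferritin heavy subunit gene (Daplx7pEVm017571), which encodes an iron store, fell by 0.91 on the log2 scale when adjusted over the list alone; it was picked after its value was seen. That list had a median of -0.21 and was not called (adjusted p = 0.0861).

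Across all genes, the smallest p-values belonged to genes of several functions outside the globins. Prostaglandin-H2 D-isomerase (Daplx7pEVm017095) had the smallest unadjusted p, with 61.7 ± 5.83 FPKM in Pale and 20.9 ± 3.95 in Red (SD, n = 4). Pathogen-related-like protein (Daplx7pEVm015745) had 2.17 ± 1.68 FPKM in Pale and 19.2 ± 5.73 in Red. These genes and those below had the same sign in 4 of 4 lakes, and none passed the threshold (limma adjusted p = 0.271 for each).

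Other genes higher in Red were Normal mucosa of esophagus-specific gene 1 protein (Daplx7pEVm026722, 1.78 ± 0.24 SE), Glutathione peroxidase (Daplx7pEVm018702, 1.17 ± 0.21), which reduces peroxides, Btb/poz domain-containing protein (Daplx7pEVm013550, 1.12 ± 0.18), Translocator protein (Daplx7pEVm018726, 1.02 ± 0.18) and Tripartite motif-containing protein 32 (Daplx7pEVm010530, 0.72 ± 0.13). Genes lower in Red were Low-density lipoprotein receptor ldl (Daplx7pEVm008956, -1.58 ± 0.20), Mucin peritrophin (Daplx7pEVm026078, -1.40 ± 0.19), Contactin-associated protein (Daplx7pEVm006652, -1.34 ± 0.15), Serpin B6 (Daplx7pEVm002307, -1.19 ± 0.13), Fibrinogen and fibronectin (Daplx7pEVm012579, -1.19 ± 0.15), Membrane glycoprotein lig-1 (Daplx7pEVm010768, -1.08 ± 0.14) and Endoglucanase (Daplx7pEVm011306, -1.05 ± 0.15). Brain chitinase and chia genes Daplx7pEVm008558 (-1.24 ± 0.18) and Daplx7pEVm022796 (-1.18 ± 0.15) were lower too. Of uncharacterized genes, Daplx7pEVm062344 (1.78) was higher, Daplx7pEVm025881 (-1.44) and Daplx7pEVm060620 (-1.76) were lower, and Daplx7pEVm061938 was listed at 0 in 4 Pale libraries and at 2.38, 4.23, 10.03 and 12.32 FPKM in Red.

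**Figure D2:**
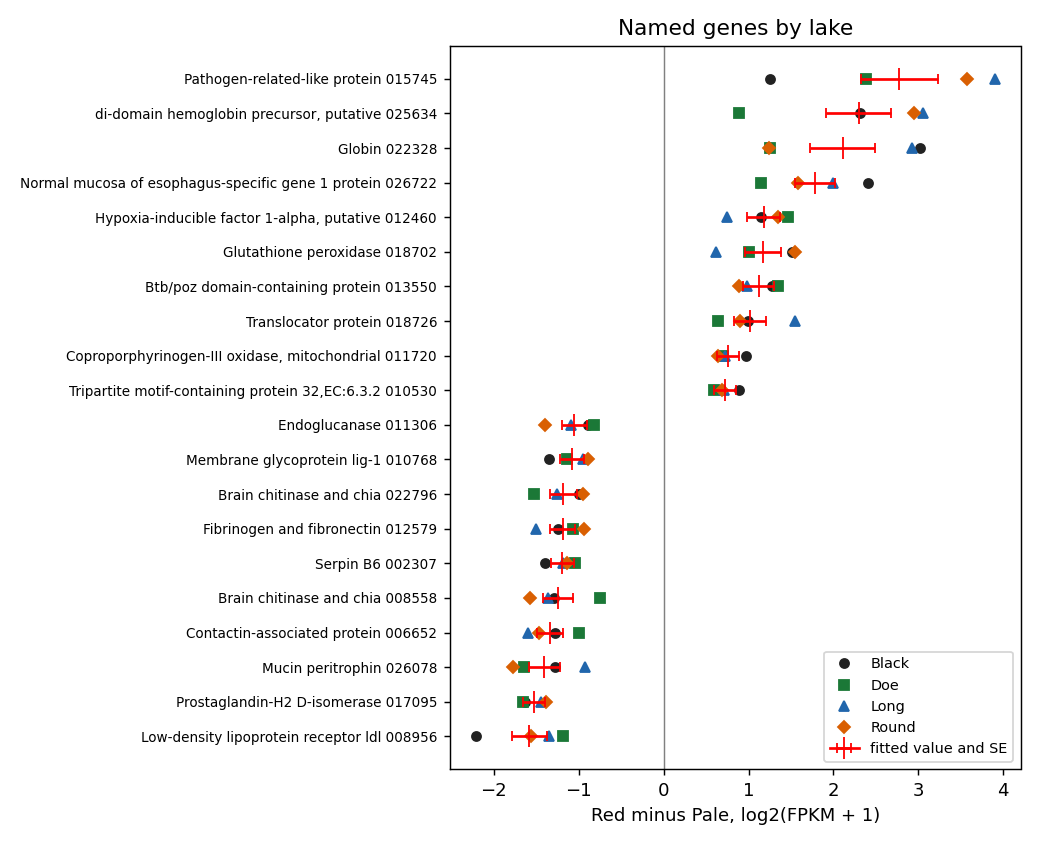
Red minus Pale difference in log2(FPKM + 1) (horizontal axis) of 20 named genes with one sign in the 4 lakes. Equally many were taken per direction, by smallest unadjusted p within that direction. They are therefore not the 20 smallest p across both directions, and the even split does not show how many genes went each way. Symbols are lakes, red bars the fitted value and its SE, and numbers the end of each identifier. No point crosses 0; Pathogen-related-like protein has the highest fitted value, 2.78.

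Of 12865 genes tested, limma called 0 at the adjusted threshold; 372 were higher and 1195 lower in Red at unadjusted p under 0.05, where chance alone would give 643. With a mean of at least 5 FPKM, and so fewer genes tested, 926 had such a p. Without the lake block, limma also called 0. The lower share depended on scaling: it was 76.3% as deposited, 57.3% (862 lower, 642 higher) with size factors and 45.8% (676 lower, 800 higher) with quantile normalization. The median log2 difference of all genes was -0.08 as deposited, -0.01 with size factors and 0.02 with quantile normalization, so changes below are to be read relative to it.

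By camera, the glycogen and glycolysis lists rose in Red and the tricarboxylic acid cycle, complex I and fatty acid lists fell; 0 of them were called with an estimated correlation. Glycogen phosphorylase (Daplx7pEVm003141), which releases glucose units from glycogen, had 66.1 ± 5.14 FPKM in Pale and 98.9 ± 12.3 in Red (SD, n = 4). The flavoprotein subunit of succinate dehydrogenase (Daplx7pEVm004881), an enzyme of the tricarboxylic acid cycle, had 57.8 ± 9.31 and 32.6 ± 6.47. No member of the glycogen, glycolysis, cycle, respiratory chain and fatty acid lists passed when adjusted over the list alone. The 14 glycogen and trehalose genes had a median of 0.22 (0.09 with no filter, 0.38 with quantile normalization) and rose by camera (adjusted p = 0.00455, but adjusted p = 0.347 with an estimated correlation); Phosphoglucomutase-1 (Daplx7pEVm006332) differed by 0.73 and Alpha,alpha-trehalose-phosphate synthase (Daplx7pEVm003790) by 0.47, while Alpha,alpha-trehalase (Daplx7pEVm007119) differed by -0.52. The 9 glycolysis genes had a median of 0.27 (0.47 with quantile normalization, 0.16 without Black) and rose by camera (adjusted p = 0.00455, but adjusted p = 0.395 with an estimated correlation). Among them were 6-phosphofructokinase (Daplx7pEVm003406, 0.51), Triosephosphate isomerase 1a (Daplx7pEVm017102, 0.48), Glyceraldehyde-3-phosphate dehydrogenase (Daplx7pEVm010997, 0.32) and Pyruvate kinase (Daplx7pEVm006933, 0.27). Glycolysis was lower in Red in Doe (mean -0.12), and its camera call was lost without the Black pair (adjusted p = 0.0613). Muscle structure (median -0.27) and digestive enzymes (-0.26), lists that mark tissues whose share can differ, fell by camera too (adjusted p = 0.00455 and 0.0209, but adjusted p = 0.395 with an estimated correlation for both).

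Of 23 tricarboxylic acid cycle genes, 21 had lower values in Red, and the list fell by camera (adjusted p = 0.0209, but adjusted p = 0.347 with an estimated correlation) and was the one list called by fry (adjusted p = 0.0197), which tests a list against no change and not against other genes. With size factors and with quantile normalization fry did not call it (0.096 and 0.46). Succinate dehydrogenase genes Daplx7pEVm015988 (-0.73) and Daplx7pEVm007897 (-0.64) were among them, as was ATP-citrate synthase (Daplx7pEVm002034, -0.47), a cytosolic enzyme that feeds lipid synthesis and matched the name pattern. Of 30 respiratory complex I genes, 29 had lower values, with a median of -0.18 (adjusted p = 0.00754, but adjusted p = 0.347 with an estimated correlation). They included the flavoproteins Daplx7pEVm015649 (-0.46) and Daplx7pEVm009583 (-0.42) and the alpha subcomplex subunits Daplx7pEVm021553 (-0.56) and Daplx7pEVm020993 (-0.46). Fatty acid oxidation (23 genes, median -0.28) fell with adjusted p = 0.0166, but adjusted p = 0.395 with an estimated correlation; examples are the acyl-CoA dehydrogenases Daplx7pEVm005409 (-0.57), Daplx7pEVm008633 (-0.46) and Daplx7pEVm009391 (-0.36) and Peroxisomal acyl-coenzyme A oxidase Daplx7pEVm004671 (-0.50). With quantile normalization these 3 lists were not called, at adjusted p = 0.321, 0.262 and 0.104, and their medians were -0.01, -0.01 and -0.10; with a pseudocount of 5 that of fatty acid oxidation was -0.17. With size factors the medians of the cycle and complex I lists were -0.10 and -0.09, and the cycle list lost its call (0.0591), as it did with a mean of at least 5 FPKM (0.165). Leaving out 1 lake also ended their calls: the cycle list without Doe or Round (adjusted p = 0.0991 and 0.116), complex I without Long or Round (0.0544 and 0.0827) and fatty acid oxidation without Round (0.087). Fatty acid synthesis and lipid storage (10 genes, median -0.33) fell with adjusted p = 0.0209, but adjusted p = 0.395 with an estimated correlation; the elongation genes Daplx7pEVm012152, Daplx7pEVm012309 and Daplx7pEVm012074 differed by -0.81, -0.75 and -0.37. Its median was -0.18 with quantile normalization and -0.22 with no filter. That call was lost without Black or Long (adjusted p = 0.0546 and 0.0862). Respiratory complexes III and IV (20 genes, median -0.21, 0.00 after quantile normalization) and ATP synthase (12, median -0.08, with a camera direction of higher) were not called, at adjusted p = 0.0938 and 0.606.

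Within the list of lactate and anaerobic end products, the genes named L-lactate dehydrogenase A chain rose in Red, while a gene named D-lactate dehydrogenase fell. Both genes named L-lactate dehydrogenase A chain, the enzyme that turns pyruvate into lactate, rose in Red when adjusted over the list alone, Daplx7pEVm012127 by 0.83 ± 0.21 (SE) and Daplx7pEVm010674 by 0.49 ± 0.14 on the log2 scale, in 4 of 4 lakes. D-lactate dehydrogenase, mitochondrial (Daplx7pEVm006010) fell by 0.62 on the log2 scale, also in 4 of 4 lakes. These 3 were picked after their values were seen, and 5 members did not pass. The list of 8 genes was not called (median -0.06, mean 0.03, camera direction higher, adjusted p = 0.531).

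**Figure D3:**
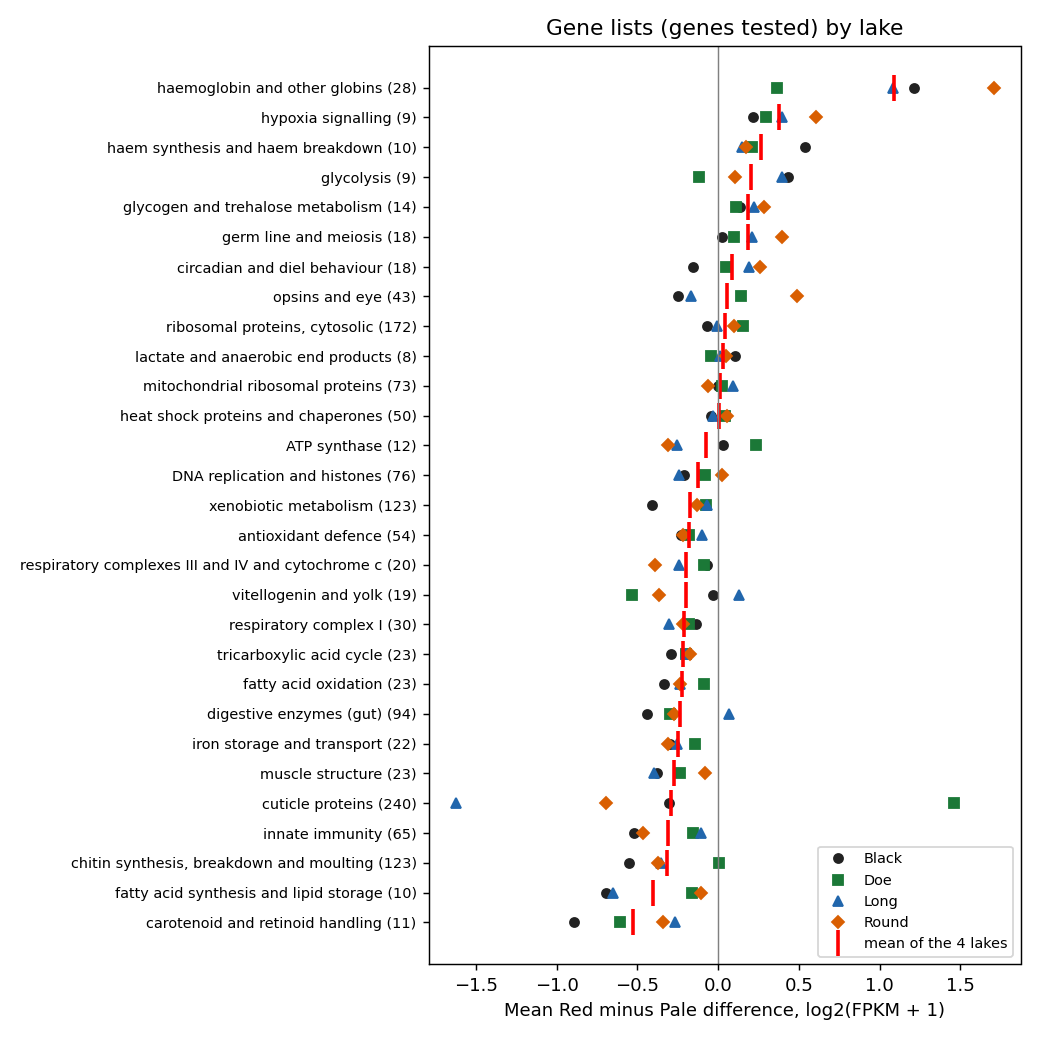
Mean Red minus Pale difference in log2(FPKM + 1) (horizontal axis) of the 29 gene lists tested, with the number of genes in brackets; symbols are lakes and red bars the mean of the 4 lakes. Globins lie highest, from 0.36 in Doe to 1.71 in Round, and cuticle proteins spread widest, from -1.62 in Long to 1.46 in Doe.

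Lists of chitin, immunity, muscle and gut fell in Red by camera, as did a list made up mostly of apolipoprotein D genes. Of the genes of chitin synthesis, breakdown and moulting, 6 fell when adjusted over the list alone and 117 did not pass, with a median of -0.23 (adjusted p = 0.00136, but adjusted p = 0.395 with an estimated correlation). Its mean in Doe was 0.005, and its median was -0.11 with no filter and -0.12 with quantile normalization. Those that fell included Brain chitinase and chia Daplx7pEVm018113 (-1.08), and Mucin peritrophin, a protein of the gut lining rather than the carapace. Of 65 innate immunity genes, 2 mannose-binding C-type lectins fell when adjusted over the list alone, Daplx7pEVm012702 (-0.88) and Daplx7pEVm011102 (-1.04), and 63 genes did not pass; lectins Daplx7pEVm019649 and Daplx7pEVm015450 differed by -0.91 and -0.86. The list had a median of -0.30 (adjusted p = 0.0053, but adjusted p = 0.395 with an estimated correlation), with -0.18 for a pseudocount of 5 and -0.19 with quantile normalization. Muscle structure (23 genes, median -0.27) fell with adjusted p = 0.00455, but adjusted p = 0.395 with an estimated correlation. Its member Troponin C 25D Daplx7pEVm019394 fell by 0.85 when adjusted over the list alone; Daplx7pEVm020872, Titin (Daplx7pEVm000215) and Troponin C at 41C (Daplx7pEVm019384) differed by -0.63, -0.57 and -0.47. Digestive enzymes (94 genes, median -0.26) fell with adjusted p = 0.0209, but adjusted p = 0.395 with an estimated correlation; Trypsin-zeta (Daplx7pEVm009303) and Alpha-amylase (Daplx7pEVm004590) differed by -0.80 and -0.79, and Carboxypeptidase B2 (Daplx7pEVm006494) by 0.64. No member passed when adjusted over the list alone, the mean in Long was 0.07, and the median was -0.12 with quantile normalization, -0.14 with no filter and -0.16 with a pseudocount of 5. All 11 genes matched by the carotenoid and retinoid patterns, 7 of them named apolipoprotein D, had lower values, with a median of -0.55 (adjusted p = 0.00455, but adjusted p = 0.39 with an estimated correlation). They included the apolipoprotein D genes Daplx7pEVm018465 (-0.77), Daplx7pEVm016442 (-0.69) and Daplx7pEVm018658 (-0.80), carriers of small lipids in general, and Beta,beta-carotene 9',10'-oxygenase (Daplx7pEVm007893, -0.46); no member passed when adjusted over the list alone, and the median was -0.28 with a pseudocount of 5. Without apolipoprotein D fewer than 5 genes remained, so carotenoid handling itself was not tested, and with a mean of at least 5 FPKM the list was not called (adjusted p = 0.0748). Without Round the immunity list was not called (adjusted p = 0.111), nor were digestive enzymes without Doe or Round (0.23 and 0.215), with a mean of at least 5 FPKM (0.165) or without the lake block (0.0536).

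Germ line, eye, mitochondrial ribosome and circadian lists rose in Red by camera, with small medians, and the cytosolic ribosomal list was called higher against a median of -0.01. No member of these 5 lists passed when adjusted over the list alone. The germ line list (18 genes, median 0.15; adjusted p = 0.00136, but adjusted p = 0.385 with an estimated correlation) had a median of 0.01 without Round, 0.23 without Doe, 0.03 with no filter, 0.24 with size factors and 0.31 with quantile normalization. Among its members were the Tudor domain-containing genes Daplx7pEVm000566 (0.62), Daplx7pEVm000836 (0.43), Daplx7pEVm000194 (0.47) and Daplx7pEVm000375 (0.40). The 2 members higher at unadjusted limma p under 0.05 carry this name. All 10 tested genes of the name were higher in Red, with a median of 0.25. How far the germ line call rests on this family was not separated. Opsins and eye (43 genes, median 0.03; adjusted p = 0.0209, but adjusted p = 0.617 with an estimated correlation) had lower means in Red in Black and Long (-0.25 and -0.17) and lost the call without the Round pair (adjusted p = 0.673) and with no filter (0.227, median -0.02); 4 rhodopsin-class receptors, Daplx7pEVm009890, Daplx7pEVm012168, Daplx7pEVm012424 and Daplx7pEVm010103, differed by 0.79, 0.94, 0.71 and 0.70. Cytosolic ribosomal proteins (172 genes) had a mean of 0.04 (-0.07 in Black) and a camera direction of higher (adjusted p = 0.024, but adjusted p = 0.509 with an estimated correlation). Of these genes, 80 carry the single name 40s ribosomal protein s9, among them Daplx7pEVm024165 (0.65), and a similar name is that of Daplx7pEVm014229 (0.53); 60S ribosomal proteins L11 (Daplx7pEVm059560) and L3 (Daplx7pEVm009317) differed by 0.72 and 0.55. Without the genes named s9 and those of ribosome biogenesis or export, the direction turned lower (median -0.11, adjusted p = 0.368). Mitochondrial ribosomal proteins (73 genes, median 0.05, mean -0.06 in Round) rose with adjusted p = 0.0233, but adjusted p = 0.347 with an estimated correlation, and Daplx7pEVm018979, Daplx7pEVm016636, Daplx7pEVm014950 and Daplx7pEVm022794 differed by 1.06, 0.46, -0.57 and -0.81. The circadian list (18 genes, median 0.07, mean -0.15 in Black) rose with adjusted p = 0.0497, but adjusted p = 0.395 with an estimated correlation; 7 members are named Cell division cycle protein, among them Daplx7pEVm007968 (0.38) and Daplx7pEVm007731 (0.44), and Timeless (Daplx7pEVm000785) and Cryptochrome-1 (Daplx7pEVm006186) differed by 0.60 and -0.75. Leaving out 1 lake ended the call of cytosolic ribosomal proteins (without Black or Doe, adjusted p = 0.0671 and 0.0787), of mitochondrial ones (without Black or Long, 0.135 and 0.0878) and of the circadian list (without Doe, Long or Round, 0.135, 0.114 and 0.195). With a mean of at least 5 FPKM neither ribosomal list was called (0.376 for each), and the mitochondrial one was also lost with no filter (0.419) and with quantile normalization (0.0563). The circadian call was also lost with size factors (0.0535), quantile normalization (0.0783), no filter (0.373), a pseudocount of 5 (0.058), no lake block (0.0652) and without the cell division cycle genes (0.506). Over the 12 alternatives of data, model and left-out lakes, medians ran from -0.035 to 0.135 for opsins (-0.01 without Doe, 0.13 without Black), from -0.082 to 0.085 for cytosolic and from -0.001 to 0.148 for mitochondrial ribosomal proteins (0.01 without Doe, -0.001 without Long), and from -0.008 to 0.192 for the circadian list (0.02 without Doe). Heat shock proteins (50 genes, median 0.03), antioxidant defence (54, -0.19), vitellogenin and yolk (19, -0.23), cuticle proteins (240, -0.39), DNA replication and histones (76, -0.02, with a mean of -0.13 and a camera direction of higher) and xenobiotic metabolism (-0.14) were not called, at adjusted p = 0.0528, 0.0893, 0.592, 0.435, 0.62 and 0.216. Heat shock proteins were called higher with size factors (adjusted p = 0.0241) and with quantile normalization (0.00872), but adjusted p = 0.32 and 0.454 with an estimated correlation in these settings; with no filter camera gave 0.176. No gene name matched the list of mitochondrially encoded genes.

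Of 29 lists tested, camera called 10 higher and 9 lower in Red. With an estimated correlation 0 were called after adjustment and 3 had unadjusted p under 0.05, and fry called 1. With size factors or quantile normalization, 0 were called by fry or with an estimated correlation. The estimates alone do not account for the lost calls. For the cycle and mitochondrial ribosomal lists they were -0.026 and -0.0072, below the preset 0.01. Yet unadjusted camera p rose from 0.0115 to 0.0684 and from 0.0137 to 0.0482. Cuticle proteins, the list that spread widest between lakes, differed by -0.30 in Black, 1.46 in Doe, -1.62 in Long and -0.69 in Round. Without Doe that list was called lower in Red (median -0.88, adjusted p = 4.42e-10), as it was with size factors (-0.33, 0.0436) and quantile normalization (-0.28, 0.0183). It had adjusted p = 0.86 with an estimated correlation as deposited, 0.695 with size factors and 0.666 with quantile normalization; without Doe this was not computed.

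In the isoform table, 1 of 23583 isoforms passed limma. Isoform Daplx7pEVm000372t56 of the non-muscle Myosin heavy chain was listed at 0 in 4 Pale libraries and at 23.58 (Black), 22.72 (Doe), 37.09 (Long) and 30.42 FPKM (Round) in Red, with adjusted p = 0.00933, while its gene differed by -0.27. Its log2 difference was 4.85 (8.13 with a pseudocount of 0.1, 2.72 with 5), and with any 1 lake left out it stayed between 4.72 and 4.95 while the call was lost (adjusted p from 0.0847 to 0.279; fewer libraries). At unadjusted p under 0.05, 582 isoforms were higher and 1662 lower, where chance would give 1179. Other isoforms higher in Red, not past the threshold (adjusted p = 0.4 each), belonged to SD07170p (Daplx7pEVm013639t6, 1.36), LSM14 A (Daplx7pEVm005717t6, 1.30), u1 small nuclear ribonucleoprotein a (Daplx7pEVm029225t5, 1.48) and Cytoplasmic dynein 1 intermediate chain (Daplx7pEVm004631t17, 1.12). Lower ones belonged to Contactin-associated protein 1 (Daplx7pEVm007500t3, -1.89, and Daplx7pEVm011086t4, -1.83), Hemocyte protein-glutamine gamma-glutamyltransferase (Daplx7pEVm003149t5, -1.56) and Apolipoprotein D (Daplx7pEVm016393t9, -1.30). C-type lectin domain family 2 member L (Daplx7pEVm019161t1) was listed at 0 in 4 Red libraries and at 2.51, 2.17, 2.76 and 2.64 FPKM in Pale.

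Within single lakes the phenotypes differed by at least 1 on the log2 scale in 1298 genes in Black (306 higher in Red, 992 lower), 1419 in Doe (723 and 696), 1753 in Long (505 and 1248) and 1168 in Round (441 and 727). These differences rest on 1 library each and have no replicate check, and their number depends on the pseudocount and the filter. In the same order of lakes it was 2281, 2356, 2810 and 2031 with a pseudocount of 0.1, 457, 523, 678 and 326 with 5, and 678, 675, 914 and 525 with a mean of at least 5 FPKM; with no filter Round had 1787. Across genes, which are not independent replicates, they correlated between lakes from -0.275 (Doe and Long) to 0.268 (Long and Round; Pearson), and from 0.02 to 0.233 by Spearman. In 21.2% of genes the sign was the same in 4 lakes (845 higher, 1882 lower in Red), where chance at equal odds of either sign would give 12.5%. The median difference of all genes was below 0 in each lake (-0.19 in Black, -0.018 in Doe, -0.073 in Long and -0.035 in Round). The split into higher and lower genes was therefore not separated from the scaling of the libraries. With no filter the share was 12.63%, a setting in which genes at 0 in both libraries of a lake have no sign.

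Animals from Black differed from the other lakes in 5 genes as analysed here, and in 0 with no filter or with a mean of at least 5 FPKM. Of the 5, 2 are named Clip-domain serine protease, a class that acts in arthropod immune cascades and was not tested as a whole by lake: Daplx7pEVm011981 had 44.23 and 31.24 FPKM there and at most 2.64 elsewhere (log2 difference 4.46 ± 0.25 SE, limma adjusted p = 0.0254), and Daplx7pEVm007976 had 17.96 and 33.07 (3.73 ± 0.27, adjusted p = 0.0369). Aspartyl beta-hydroxylase variant (Daplx7pEVm058960) differed by 4.00 ± 0.23 and the uncharacterized gene Daplx7pEVm014256 by 3.08 ± 0.22, while the uncharacterized gene Daplx7pEVm019732 differed by -4.69 ± 0.30. The contrasts for Doe, Long and Round called 0 genes, with 1310, 991 and 1067 at unadjusted p under 0.05, and the F test over lakes called 0 of 12865, with 1273 at unadjusted p under 0.05; chance would give 643 in each. With no filter or a mean of at least 5 FPKM the 5 genes had adjusted p from 0.0721 to 0.12. The lake contrasts called 3 genes with a pseudocount of 0.1, 13 with 5 and 10 without the phenotype term. Of the 5 genes named here, 2 kept their call with a pseudocount of 0.1, 3 with 5 and 3 without the phenotype term. With a pseudocount of 5 the log2 difference of Daplx7pEVm011981 was 2.85, and Daplx7pEVm007976 was not called with size factors (0.058) or quantile normalization (0.0614). With 1 library left out, the lake contrasts called 19 genes without Doe Red, 1 without Doe Pale and 0 without any of the other 6.

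Of the gene lists, camera called cuticle proteins higher in Black (median difference 0.84, adjusted p = 2.08e-06), globins lower in Round (-0.46, adjusted p = 2.08e-06) and DNA replication and histones higher in Round (0.32, adjusted p = 0.000384). There were 21 list calls by lake (4 in Black, 7 in Doe, 5 in Long and 5 in Round). Of these, the 3 above held with any 1 of the 8 libraries left out. The median of cuticle proteins in Black moved to 0.50 without Doe Pale. For globins in Round it ran from -0.76 without Round Red to -0.335 without Long Pale. For DNA replication and histones in Round it fell to 0.226 without Round Red. For globins the 2 libraries of Round lay apart, with list means after removal of the phenotype means of -0.845 in Round Pale and -0.231 in Round Red. With an estimated correlation 0 of the 21 list calls by lake were made (adjusted p = 0.838 for each), and with no filter camera made 12 calls. Cuticle proteins were also called higher in Doe (0.25) and lower in Long and Round (-0.85 and -0.20), but there the libraries of a lake lay apart. List means after removal of the phenotype means were -0.64 in Doe Pale and 1.11 in Doe Red, -0.01 in Long Pale and -1.34 in Long Red, and 0.04 in Round Pale and -0.36 in Round Red, against 0.60 and 0.59 in Black. Without Doe Red the list was called lower in Doe (-0.81, adjusted p = 7.05e-05), and without Long Red the Doe call was lost (0.0737). The Long call was lost without Long Red (median 0.20, adjusted p = 0.805), and the Round call without Doe Red or Round Red (0.257 and 0.342). Globins were called higher in Doe (0.45, adjusted p = 0.0225), and this was lost without Doe Pale (0.791), Black Pale (0.13) or Long Red (0.0778). Where a call was lost with fewer libraries, the median did not always shrink. Without Doe Red, complex I in Doe went from -0.189 to -0.237 and muscle in Doe from -0.365 to -0.348. Complex I in Long went from 0.072 to 0.070 without Long Pale, while opsins in Round turned from -0.182 to 0.106 without Round Pale. The remaining calls were each lost without at least 1 library, given here with the one of highest adjusted p. They were muscle (higher in Black, lost without Doe Red, 0.17; lower in Doe, without Doe Red, 0.116), opsins (higher in Black, without Black Pale, 0.251; higher in Long, without Long Pale, 0.268; lower in Round, without Round Pale, 0.632) and germ line (higher in Black, without Black Pale, 0.264; lower in Long, without Long Pale, 0.262). Complex I was called lower in Doe (lost without Doe Red, 0.224) and higher in Long (without Long Pale, 0.434), and cytosolic ribosomal proteins higher in Doe (without Doe Red, 0.257) and lower in Long (without Long Red, 0.167), with a median of -0.04 in both. Fatty acid synthesis and digestive enzymes were called higher in Doe (lost without Doe Red, 0.186, and without Doe Pale, 0.579) and haem synthesis lower in Round (without Round Red, 0.458).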

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

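Of 252 groups of 4 libraries examined, 13 had 1 library far from the other 3 by Dixon's ratio (critical value for 4 values exceeded), as many as the 13 that chance would give. Doe Pale stood apart in 4 genes: di-domain haemoglobins Daplx7pEVm058987 (192.95 FPKM, the others at most 29.51; ratio 0.884), Daplx7pEVm023442 (ratio 0.897) and Daplx7pEVm013636 (ratio 0.907) were high, and succinate dehydrogenase Daplx7pEVm004881 was low (43.84 FPKM, the others at least 62.0; ratio 0.951). Haemoglobin Daplx7pEVm013392 was high in Long Pale (313.97 FPKM; ratio 0.855), and Mucin peritrophin Daplx7pEVm026078 in Round Pale (52.63 FPKM; ratio 0.855). Among Red libraries, Hypoxia-inducible factor 1-alpha, putative was low in Black (1.85 FPKM against 2.77 to 2.90; ratio 0.876). Troponin C 25D Daplx7pEVm019394 was low in Doe Red (ratio 0.931), Troponin C at 41C was high in Black Red (ratio 0.977) and Timeless was high in Long Red (ratio 0.904). Cell division cycle protein Daplx7pEVm007731 was low in Long Pale (ratio 0.921). Isoform Daplx7pEVm029225t5 was above 0 in Round alone of the Pale libraries (ratio 1), and isoform Daplx7pEVm016393t9 was high in Doe Red (ratio 0.977).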

How the results depend on the processing

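The list cleaned of members of other function, fry and an estimated correlation under other scalings, and all settings for lists by lake and for variance shares, were chosen after seeing the data. The count of 0 genes for Red against Pale held under each setting run. Of the 19 lists called by camera, 6 were called under each of the 12 settings of data, model and left-out lakes: globins (medians from 0.65 to 1.55), hypoxia signalling (0.16 to 0.43), glycogen and trehalose (0.09 to 0.38), chitin (-0.33 to -0.11), muscle (-0.37 to -0.19) and germ line (0.01, without Round, to 0.31). With an estimated correlation 0 lists were called and with fry 1, and globins gave adjusted p = 0.347 and 0.091 with the same median of 1.21; with size factors and quantile normalization fry and an estimated correlation called 0 lists, and globins gave 0.0857 and 0.128 by fry and 0.32 and 0.454 with the correlation (medians 1.30 and 1.23). Without a lake the number of lists ran from 12 to 16. With a mean of at least 5 FPKM, 926 genes had unadjusted p under 0.05 (fewer genes tested). Genes differing within a lake numbered 2281, 2356, 2810 and 2031 (Black, Doe, Long, Round) with a pseudocount of 0.1, 457, 523, 678 and 326 with 5, and 678, 675, 914 and 525 with a mean of at least 5 FPKM; with no filter Round had 1787. With no filter the share of genes with one sign was 12.63%. Lake contrasts called 3 genes with a pseudocount of 0.1, 13 with 5, 0 with no filter or a mean of at least 5 FPKM and 10 without the phenotype term, and from 0 to 19 with 1 library left out. Of the 5 genes named for Black, 2 kept their call with a pseudocount of 0.1, 3 with 5 and 3 without the phenotype term. The F test over lakes called 1 gene with a pseudocount of 5. Lists called by lake numbered 12 with no filter and from 11 to 23 with 1 library left out (11 without Doe Pale or Long Red). The isoform count was 0 without any lake. Directions of lists that were not called turned as follows: ATP synthase (-0.08) and DNA replication (-0.022) under fry, DNA replication with no filter (-0.068), vitellogenin with a mean of at least 5 FPKM (-0.23), and complexes III and IV with quantile normalization by each test (0.004). The cytosolic ribosomal list turned lower (-0.11) without the genes named s9 and those of ribosome biogenesis or export. Without a lake, camera directions turned for ATP synthase (medians over the 4 lakes left out from -0.112 to 0.033), vitellogenin (-0.283 to -0.18), cuticle proteins (-0.883 to 0.013) and DNA replication (-0.14 to -0.034). Genes near 0 that changed sign were Alpha-globin transcription factor CP2 (0.053 and 0.165 with size factors and quantile normalization) and, without a lake, Daplx7pEVm017006 (-0.277 to 0.223), Cytoglobin-2 (-0.156 to 0.164) and Daplx7pEVm013242 (-0.22 to 0.542). Lists not called as deposited that camera called under an alternative were iron (no filter, 0.0115, and without members of other function, 0.0489), complexes III and IV (no filter, 0.00796, and without Black, 0.0259), antioxidant defence (no filter, 0.0072, and without Long, 0.0381), xenobiotic metabolism (mean of at least 5 FPKM, 0.0486), heat shock (besides both scalings, a pseudocount of 0.1, 0.0472, a mean of at least 5 FPKM, 0.0486, no variance trend, 0.0492, and no lake block, 0.0456) and cuticle proteins; with an estimated correlation on the values as deposited 0 of them were called. The cause was not tested except where given. Without the lake block the counts were the same for genes (0) and isoforms (1), and 18 lists were called; digestive enzymes and the circadian list were lost and heat shock proteins gained. Camera has no robust option and the exact test no variance model, so those settings were not run for them. With a mean of at least 5 FPKM the haem list, and without members of other function the carotenoid list, had fewer than 5 genes and gave no value. Unknown read depth limits genes near 1 FPKM.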

Other observations

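The tests of read sharing, scaling, depth, moult stage and isoform assignment, and the grouping by name, were chosen only after the results were seen. The splits, the swap and the count of all-or-none isoforms were set beforehand. The conditions on spread used for the swap and the isoform assignment were added after their values were seen.

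Genes were also grouped by shared names. Of families of at least 8 genes, camera called 12 higher and 13 lower in Red and left 98 uncalled; these counts include families of the fixed lists, such as di-domain hemoglobin and brain chitinase, and 0 were called with an estimated correlation (smallest adjusted p = 0.874). The families named here kept their direction and call with size factors and with quantile normalization. Contactin-associated protein, a cell adhesion family of nervous tissue in vertebrates, had lower values in 38 of 42 genes (median -0.49, adjusted p = 3.31e-08), and Contactin-associated protein 1 in 29 of 32 (median -0.51, adjusted p = 0.000476). Neurexin IV (28 genes, median -0.48) and Ankyrin (28 genes, -0.34, with 27 lower) were lower as well, at adjusted p = 0.0182 and 0.00169. Caprin-2 (13 genes, -0.64) and Complement C1q tumor necrosis factor-related protein (27 genes, -0.47) were lower at adjusted p = 0.00463 and 0.0114. JmjC domain-containing histone demethylation protein (30 genes, 0.18, adjusted p = 0.00077) and the 26S proteasome non-ATPase regulatory subunits (12 of 12 genes higher, median 0.10, adjusted p = 0.0182) were higher. Globin totals varied 3.7-fold among Pale libraries and 1.38-fold among Red ones; this difference in spread was not tested.

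Globins were higher in Red in each lake, and reads shared between near-identical copies would move values between genes and leave the family sum in place, but the sum differed by 1.32 ± 0.32 (SE, log2), above the 0.3 set as the bound. Scaling between libraries is argued against too, since the difference was 1.41 ± 0.33 after median-of-ratios scaling. The 8 splits that part all 4 lake pairs are too few for a share under 0.05. The real camera p was 5.29e-12 and the smallest of the other 7 splits was 3.49e-09. That split exchanged the labels of Doe alone and otherwise equals the real contrast. Camera p ran from 3.49e-09 to 0.179 with 1 lake exchanged and from 0.000359 to 0.864 with 2. Of the 24 splits that part 2 pairs, those with Red and Pale of Black and Round as labelled gave 2.41e-17, which is the real contrast in these lakes alone. The phenotype itself stays open as an explanation, as a hypothesis.

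Cuticle proteins were higher in Red in Doe (1.46 ± 0.14, SE over 240 genes) and lower in Long (-1.62 ± 0.14), a difference between lakes that was not tested. The SEs over genes in this paragraph take genes as independent, but the estimated correlation of this list was 0.3. With 1 pair per lake they are too small and say nothing of the spread between pools. Unequal depth is argued against, because the Black pair, with a depth ratio of 1.86, differed by only -0.30 ± 0.08 while those of Doe and Long had ratios of 0.976 and 0.982. A swap of the Doe labels cannot be told apart. Of the 1544 genes with unadjusted limma p under 0.05 in the other 3 lakes, 59.1% had the same sign in Doe, against 56.2% of all genes. This share was above the bound of 55 set beforehand. In other splits it had an SD of 13.4, from 23.3 to 76.7. Those splits include exchanged labels of the left-out lake, which only turn same signs into opposite ones. That SD is therefore no error of the Doe share, and without one the share does not decide. Exchanging the Doe labels alone lowered genes at unadjusted p under 0.05 from 1567 to 946 and called lists from 19 to 6. Taken for each lake in turn, the share was lowest for Doe, with 72.6% for Black, 65.6% for Long and 69.2% for Round. Summed globins (3444 FPKM in Pale, 5320 in Red) and Hypoxia-inducible factor 1-alpha, putative (0.41 and 2.90 FPKM) differed in Doe in the same direction as in the other lakes. Moult stage may differ between pools, and this cannot be told apart either. The 108 chitin and moulting genes not shared with the cuticle list showed no clear correlation with the cuticle mean over 8 libraries. Pearson r was 0.439 (exact permutation p = 0.274) and Spearman rho 0.333 (exact p = 0.428). Without Long Red and Doe Red r was 0.47, and all these values took libraries as unpaired. Within Black, Doe, Long and Round these chitin genes differed by -0.51, -0.06, -0.22 and -0.34. The lake of origin stays open and was not tested.

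The non-muscle myosin isoform was the one isoform called. All-or-none assignment of reads among isoforms, unrelated to phenotype, is a candidate explanation: 4 isoforms were at 0 in all libraries of one phenotype and at 1 FPKM or more in all of the other, while another of the 8 splits gave 7. Assignment among the gene's 61 isoforms cannot be told apart from a real switch: the other isoforms were lower in Red by at least 50% of its gain in 3 lakes, but their differences varied between lakes with an SD of 147 FPKM against a mean gain of 28.5 FPKM, which leaves that test without force. The 8 splits are too few for a share under 0.05; the real split called 1 isoform and the highest of the other 7 called 0.

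For the other counts the same 8 splits are also too few. The real split gave 1567 genes at unadjusted p under 0.05, and the highest of the other 7, with Doe alone exchanged, gave 946. The real split called 19 lists, against at most 11 in the others, with Long alone exchanged. It called 0 genes at the adjusted threshold, as did each of the 8. Splits that exchange 2 lakes, and so share less with the real contrast, gave 285 to 523 genes and 2 to 5 lists. Of the 24 splits that part 2 pairs, 1 contrast of Doe Red and Long Pale with Doe Pale and Long Red called 62 genes and 45 isoforms. It points to a structure of the samples in which Red minus Pale was unequal in Doe and Long for these genes; what it comes from was not tested.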
